A study of Oryza sativa with 90 samples.

How the data were processed

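Values of 90 rice libraries, of RNA-seq, small RNA-seq and RIP-seq, were taken from the deposited tables. Anthers of stages 4 to 6, 7 to 8 and 9 came from wild type and ago1d plants at 22 °C or 28 °C, and spikelets of the same stages from plants carrying AGO1d::AGO1d-FLAG, with 3 biological replicates each per the design text. Per the labels' protocols, plants were moved from the field to growth chambers early in anther development. Groups, comparisons, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined, except where stated below. The small RNA library of wild type at stages 4 to 6 and 22 °C, replicate 1, has 22 °C in its title and 28 °C in its treatment field; it was grouped by its title.

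RNA-seq values are FPKM per gene as deposited by the authors, and per the submitters' processing notes CASAVA, HISAT2, Cufflinks, Bowtie and featureCounts were used in the series, with no versions given. The PHAS and RIP values are a score per locus or per sequence deposited by the authors: RPM per the file names, rounded to whole numbers. The library total to which RPM refers is not stated, and no table gives counts, so the depth per library is unknown and no counting interval was computed. Summed RPM per library is a sum over the listed loci or sequences and not a depth. The genome build was not given in the sources used here, so coordinates are printed as the tables give them. Deposited columns that hold means over libraries were not used. No pair of libraries within a table had identical values.

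Values were transformed to log2(value + 1) and tested with limma 3.58.1 (trended variance) in R 4.3.3 with the package data.table (version 1.17.8). Features with a value of at least 1 in at least 3 libraries of the fit were tested, and a Benjamini-Hochberg adjusted p under 0.05 was a call. Genes were fitted per stage group over its 12 RNA-seq libraries, PHAS loci over all 36 small RNA libraries, and RIP against input over the 6 libraries of a stage group. The contrasts were ago1d against wild type at each temperature, 22 °C against 28 °C in each genotype, and the genotype by temperature interaction, defined as the genotype difference at 22 °C minus that at 28 °C. For 24-PHAS loci, 22 °C against 28 °C in ago1d and the interaction were added after the data had been seen. Summed PHAS RPM was compared with a 2-sided exact permutation test within the 3 stage groups, with 8000 permutations on log2 sums. A single stage group of 3 against 3 cannot give an exact p below 0.1. The 5′ nucleotide shares and summed RIP RPM were compared with a 2-sided exact sign-flip test over 9 pairs of RIP and input (512 sign flips), adjusted over the 4 nucleotides. Sums, permutations and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

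The RIP tables hold sequences of 18 to 26 nt. The RIP results use sequences of exactly 21 nt or exactly 24 nt. This reading was fixed only after the length composition, and exploratory counts over all lengths, had been seen; all lengths are an alternative. RIP and input libraries with the same number come from 1 lysate, since the input was an aliquot of it per the design text. Their deviations from the group means had correlations from -0.062 to 0.114, and the pairing as a block changed no RIP call count by over 1.5 times.

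The 10 gene lists held 147 members: small RNA machinery, anther transcription factors and receptors, tapetum and pollen wall, meiosis, heat shock proteins and factors, cold and dehydration response, photosynthesis (green tissue markers), other floral organ and meristem markers, stamen identity and mature pollen markers. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 9 lists tested per contrast and stage group. Too few mature pollen markers passed the filter for a test. Of 135 list tests, 59 were called with the preset correlation and 5 with an estimated one: photosynthesis in ago1d against wild type at 28 °C and in the interaction, each at stages 4 to 6 and 7 to 8, and heat shock in the interaction at stages 7 to 8. Members carry a second count, adjusted over the list alone, which was made over the tested members of each list.

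The files use gene identifiers without names, and the reference table (assembly ASM3414082v1) carries no such identifiers. Symbols were therefore assigned by hand from general knowledge and checked against the reference table: an entry with the symbol had to lie on the chromosome the identifier names and within 2.5 Mb of the place interpolated from the other members. Of the members, 87 were placed, 57 had a symbol that is not in the reference table and 3 were contradicted and left out. Only placed members are named, and the rest are counted. Named list members were those past the threshold with the largest changes, up to 4 per list. For other genes the rule named 5 per direction with a mean of at least 5 FPKM and groups that did not overlap, but because the files pair no names with them at most 2 identifiers per direction are printed. Up to 4 PHAS loci and 3 phasiRNAs per direction were named, at a mean of at least 10 RPM. Named loci that recur over comparisons were preferred in the text after their values were seen. Without a genome, phasiRNAs were not mapped to loci.

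The steps were tested on simulated data with 200 changed rows for genes and for 21-PHAS loci. For 21-nt and 24-nt phasiRNAs in RIP, 196 and 194 rows were changed. At a log2 change of 1, the gene test found 79%, 75% and 63% of changed genes at the 3 stage groups, with 6.45%, 5.49% and 3.11% false calls among all calls, and at a log2 change of 2 it found 95%, 97% and 93%. For 21-PHAS loci 55% and 96% were found, and for 24-PHAS loci 50% and 100% of 12 changed loci. False calls among all calls were 3.82% for 21-PHAS loci and 10% (1 of 10) for 24-PHAS loci. For RIP at stages 7 to 8, the test found 4.08% and 6.12% of changed 21-nt phasiRNAs and 37.4% and 66.3% of 24-nt ones. Of all RIP calls, 9.09% (1 of 11) were false at 21 nt and 8.26% (9 of 109) at 24 nt. Most simulated changes of single 21-nt phasiRNAs thus passed undetected. The adjusted p depends on the share of changed rows, here 196 of 12648, while 4520 of 12657 were called in the real data. The 21-nt shares found therefore do not carry over to the real RIP calls. Simulated levels under a log2 value of 2 were raised to 2. With no change simulated there were 0 or 1 calls. Of 100 simulations without a shift, 2 gave a permutation p and 6 a sign-flip p under the threshold of 0.05, and with a shift all 100 did.

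Alternatives were a pseudocount of 0.1, no filter on low values, rescaling of libraries to the same median log2 value, the replicate number as a block, each library left out in turn, the 12 libraries of a stage group alone for PHAS loci, the median over loci and the sum without the 10 highest loci for PHAS sums, the share of sequences for the 5′ nucleotide, and an estimated correlation for lists. Added after seeing the data were list members placed by symbol and position alone, all lengths in the RIP tables, stage groups left out of the RIP sums and the block for lists. The splits of samples used every division of 3 against 3 (10) and 100 drawn divisions for the interactions, made within each temperature after the genotype difference shared by both temperatures had been removed from each gene or locus.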

Results

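The series measured polyadenylated RNA, small RNA and AGO1d-bound small RNA in rice anthers and spikelets, to address how the Argonaute protein AGO1d acts in phased small interfering RNAs (phasiRNAs) and in fertility at different temperatures. PhasiRNAs of 21 nt and 24 nt are cut in register from long reproductive transcripts, and the loci that give rise to them are called 21-PHAS and 24-PHAS loci. The 90 libraries comprised 36 of RNA-seq, 36 of small RNA-seq and 18 of RNA immunoprecipitation (RIP) with its input. RNA-seq and small RNA-seq covered anthers at stages 4 to 6, 7 to 8 and 9 from wild type and an ago1d knockout grown at 22 °C or 28 °C, with 3 replicates in each group. RIP used spikelets of plants carrying FLAG-tagged AGO1d, with 3 RIP and 3 input libraries at each of the 3 stage groups. Sequencing depth is unknown, because the tables hold FPKM or rounded RPM, a read number scaled per library, and no counts. Summed FPKM per RNA-seq library ran from 583412 to 751693, summed 21-PHAS RPM from 70563 to 247794 and summed 24-PHAS RPM from 1929 to 16463.

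AGO1d transcript, the knocked-out gene (LOC_Os06g51310), was low in every library labelled ago1d and high in every library labelled wild type. In wild type at 22 °C it stood at 149.7 ± 17.3 FPKM (SD, n = 3) at stages 4 to 6, 116.1 ± 9.18 at stages 7 to 8 and 144.1 ± 22.0 at stage 9. In ago1d at 22 °C the levels were 13.1 ± 3.62, 8.42 ± 1.06 and 11.1 ± 1.62 FPKM. At 28 °C wild type had 111 ± 5.18, 84.6 ± 2.53 and 115.5 ± 3.43 FPKM, and ago1d had 3.82 ± 3.04, 2.88 ± 0.951 and 5.23 ± 3.26. The log2 differences were -3.44, -3.64 and -3.58 at 22 °C and -4.73, -4.50 and -4.35 at 28 °C. Within ago1d, AGO1d was higher at 22 °C than at 28 °C at stages 4 to 6 (log2 1.71, adjusted p = 0.0247, limma) and stages 7 to 8 (8.42 against 2.88 FPKM, adjusted p = 0.00166), and at stage 9 the difference of 1.08 did not pass (adjusted p = 0.0615). Wild type moved the same way at the first 2 stage groups without passing (log2 0.42 and 0.45, limma adjusted p = 0.516 and adjusted p = 0.0663). The genotype by temperature interaction of AGO1d did not pass there (limma adjusted p = 0.455 and adjusted p = 0.113).

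**Figure D1:**
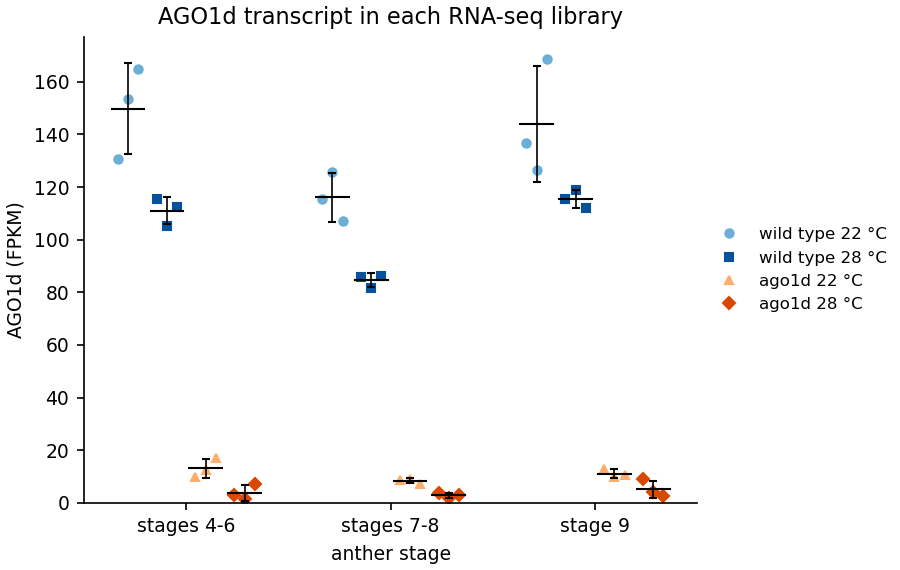
AGO1d level in FPKM (vertical axis) of each of the 36 RNA-seq libraries by anther stage; points are libraries, horizontal lines group means and bars 1 SD (n = 3). The ago1d libraries lie between 1.28 and 17.0 FPKM and the wild-type libraries between 81.7 and 168.7 FPKM.

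At 28 °C, the clearest difference between ago1d and wild type was in photosynthesis genes. All 12 tested members of that list fell at every stage, with median log2 changes of -2.65, -3.07 and -2.87, and all 12 also passed when adjusted over the list alone. CAB1R, which encodes a chlorophyll a/b-binding protein of the light-harvesting complex, stood at 16.3 ± 18.7 FPKM in ago1d against 742.5 ± 104.3 in wild type at stages 4 to 6 (n = 3 each). Its log2 changes at the later stage groups were -6.14 and -5.46, and those of CAB2R, of the same family, at the 3 stage groups were -4.71, -4.24 and -3.59. The list test of photosynthesis kept its call at the first 2 stage groups (adjusted p = 0.0376 and adjusted p = 0.034 with an estimated correlation) and lost it at stage 9 (adjusted p = 0.33 with an estimated correlation). Of the 12, CAB1R and CAB2R were the 2 whose symbol and position could be checked. With these alone the list lost its call at the first 2 as well (adjusted p = 0.0636 and adjusted p = 0.102 with an estimated correlation). Markers of other floral organs had medians of 0.09, 0.08 and 0.33 and none of their 7, 8 and 8 tested members passed limma's test, with 1, 2 and 2 at an unadjusted p under 0.05.

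Some genes of the tapetum and pollen wall differed between ago1d and wild type at 28 °C, with calls that were lower at stages 4 to 6 and mostly higher at stage 9. The list was not called at any stage group with an estimated correlation, and no test compared the stage groups. At stages 4 to 6, 4 of 12 tested members fell in ago1d (adjusted over the list alone, 4 fell and 1 rose), with adjusted p = 0.32 with an estimated correlation. At stages 7 to 8, 0 of 18 passed limma's test over all genes, while 14 were lower at an unadjusted p under 0.05 and 14 when adjusted over the list alone, with a median of -1.43 (adjusted p = 0.282 with an estimated correlation). At stage 9, 14 of 20 rose and 1 fell (adjusted over the list alone, 14 and 2), with a median log2 change of 2.06 (adjusted p = 0.33 with an estimated correlation). AP37, an aspartic protease linked to tapetal cell death, was at 261.8 ± 151.7 FPKM in ago1d and 19.0 ± 28.7 in wild type (log2 4.85). RTS, a tapetal gene needed for male fertility, was the member that fell, from 956.4 ± 280.4 to 25.96 ± 44.96 FPKM. Among anther transcription factors and receptors at stage 9, 4 of 11 rose and 2 fell (adjusted over the list alone, 6 and 3). PTC1, a PHD-finger regulator of the late tapetum, changed by 3.78 on the log2 scale, the tapetal factor TDR by 1.24 and TDL1A, a ligand in early anther patterning, by -0.80. The tapetal bHLH factor EAT1 fell by 1.88 on the log2 scale at stages 7 to 8 and TDL1A rose by 0.96, the 2 of 11 members that passed (the same number adjusted over the list alone).

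Some heat shock genes were lower in ago1d at 28 °C at the later stages. At stages 7 to 8, 3 of 15 members fell (3 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation), namely the heat stress factor HSFB2c (log2 -1.75), HSP17.9 (-1.18) and the HSP90 gene HSP81-1 (-0.69). At stage 9, 7 of 14 fell (9 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation), among them HSP24.1 (-2.59), HSP17.9 (-1.94) and HSP16.9B (-1.50). Of the meiosis list, 2 of 19 members rose at stages 7 to 8 (6 adjusted over the list alone, adjusted p = 0.45 with an estimated correlation). They were DMC1A, a meiotic recombinase (log2 0.92), and PAIR2, a chromosome axis protein (0.48). In the small RNA machinery, AGO2 fell at stages 7 to 8 (log2 -0.71), as 1 of 25 members tested (1 adjusted over the list alone). At stage 9, 2 of 27 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation), and the 2 that rose were AGO18 (0.61) and DCL4 (0.60), the Dicer of 21-nt phasiRNAs.

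Across all genes tested at 28 °C, limma called 472 lower and 363 higher of 21243 at stages 4 to 6, 769 and 716 of 21666 at stages 7 to 8, and 1866 and 2208 of 22532 at stage 9. Of the genes tested, 22.8%, 23.1% and 38.5% had groups that did not overlap, against 10% by chance for 3 against 3. With single libraries left out the calls numbered 495 (without wild type 28 °C replicate 3) to 869 at stages 4 to 6. They numbered 1030 to 2359 (without wild type 28 °C replicate 2) at stages 7 to 8, and 2108 (without ago1d 28 °C replicate 2) to 5016 (without ago1d 28 °C replicate 1) at stage 9.

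At 22 °C, far fewer genes differed between ago1d and wild type, and photosynthesis genes were not among them. None of the 12 photosynthesis members passed limma's test at any stage, with 1, 0 and 0 at an unadjusted p under 0.05 and medians of -0.17, -0.12 and -0.31. Heat shock genes were higher in ago1d at stages 7 to 8, where 4 of 15 rose (13 adjusted over the list alone, adjusted p = 0.0525 with an estimated correlation, or 0.0444 with its 14 placed members alone). The list's median at stages 4 to 6 was 1.18, where 0 of 14 passed limma's test and 4 had an unadjusted p under 0.05 (adjusted p = 0.545 with an estimated correlation). One library stood apart there: the median log2 level of the list was 7.31 in ago1d replicate 1, 4.57 and 2.8 in replicates 2 and 3, and 2.56 to 3.41 in wild type. The 4 that rose at stages 7 to 8 were HSP17.4, at 56.9 ± 39.5 FPKM against 7.71 ± 2.13 (log2 2.53), the heat stress factors HSFA2c (1.48) and HSFA2d (1.09), and HSP26.7 (0.88). Also there, 3 of 18 tapetum and pollen wall genes fell (12 adjusted over the list alone), with a median log2 change of -2.08 and adjusted p = 0.0707 with an estimated correlation. Replicates 2 and 3 of ago1d carried this, with median log2 levels of the list of 3.57 and 3.72. Replicate 1 was at 5.91, next to wild type at 5.97 to 7.21. AP37 was at 2.11 ± 2.14 FPKM in ago1d and 49.3 ± 28.5 in wild type (log2 -4.07). DMC1A was higher in ago1d at stages 7 to 8 (log2 0.98), as 1 of 19 meiosis genes tested (2 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). At stage 9, AGO3 (0.85) and TIP2, a bHLH factor of the tapetum (0.75), were higher, within lists of which 2 of 27 and 1 of 11 members rose (2 and 3 adjusted over the list alone).

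A small set of genes was near 0 in wild type and abundant in ago1d whatever the temperature. LOC_Os03g02470 was at 145.9 ± 6.44 FPKM in ago1d against 0.016 ± 0.028 in wild type at stages 4 to 6 and 22 °C, and at 191.2 ± 9.67 against 0.014 ± 0.025 at 28 °C. LOC_Os01g35330 was at 186.5 ± 6.202 FPKM against 0.085 ± 0.148 at 22 °C, and at 202.5 ± 4.47 against 0.160 ± 0.041 at 28 °C. The reference table does not pair these identifiers with names. Over all genes at 22 °C, limma called 16 lower and 105 higher at stages 4 to 6, 83 and 166 at stages 7 to 8, and 67 and 281 at stage 9. Of the genes called higher at 22 °C, 96, 122 and 192 were also higher at 28 °C, against 1.79, 5.49 and 27.5 for independent lists. These comparisons share no libraries, but both take the spread of each gene from the same fit. Genes of low spread are thus more readily called in both, so independent lists are not an exact baseline. With single libraries left out, the calls at stages 7 to 8 ranged from 131 (without ago1d 22 °C replicate 3) to 237. At stage 9 they ranged from 155 (without wild type 22 °C replicate 1) to 1218 (without ago1d 22 °C replicate 3).

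The interaction tested whether the difference between genotypes itself differed between 22 °C and 28 °C. Photosynthesis genes gave the clearest case: 9, 11 and 6 of 12 members had an interaction at the 3 stage groups, all positive, and 12 at each when adjusted over the list alone. With an estimated correlation the list kept its call at the first 2 (adjusted p = 0.0351 and adjusted p = 0.0166 with an estimated correlation) and not at stage 9 (adjusted p = 0.244 with an estimated correlation). With CAB1R and CAB2R alone it kept the call at stages 7 to 8 (adjusted p = 0.0294 with an estimated correlation) and not at stages 4 to 6 (adjusted p = 0.0572 with an estimated correlation). CAB1R had log2 interactions of 5.68 at stages 4 to 6 and 5.15 at stage 9. At stages 7 to 8, 6 of 15 heat shock genes had a positive interaction (12 adjusted over the list alone, adjusted p = 0.0166 with an estimated correlation), led by HSP17.4 (3.21), HSFB2c (2.53), HSP17.9 (1.72) and HSFA2c (1.71). AGO2 had a positive interaction there (0.98), as 1 of 25 genes of the small RNA machinery. At stage 9, 4 of 20 tapetum and pollen wall genes had a negative interaction (14 lower and 1 higher adjusted over the list alone, adjusted p = 0.244 with an estimated correlation). CYP703A3, which hydroxylates fatty acids for the pollen wall, was among them (log2 -3.32), and PTC1 (-3.43) and TDL1A (1.71) had interactions in the anther transcription factor list, where 1 of 11 was positive and 2 were negative. HSP17.9 was the 1 heat shock gene at stage 9 (1.53; 7 adjusted over the list alone).

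Over all genes, limma called 9 negative and 124 positive interactions at stages 4 to 6, 68 and 234 at stages 7 to 8, and 236 and 346 at stage 9. The stage 9 total of 582 was 192 without ago1d 28 °C replicate 2 and 1958 without ago1d 22 °C replicate 3. With no filter on low values the totals were 80 in place of 133 at stages 4 to 6 and 351 in place of 582 at stage 9.

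**Figure D2:**
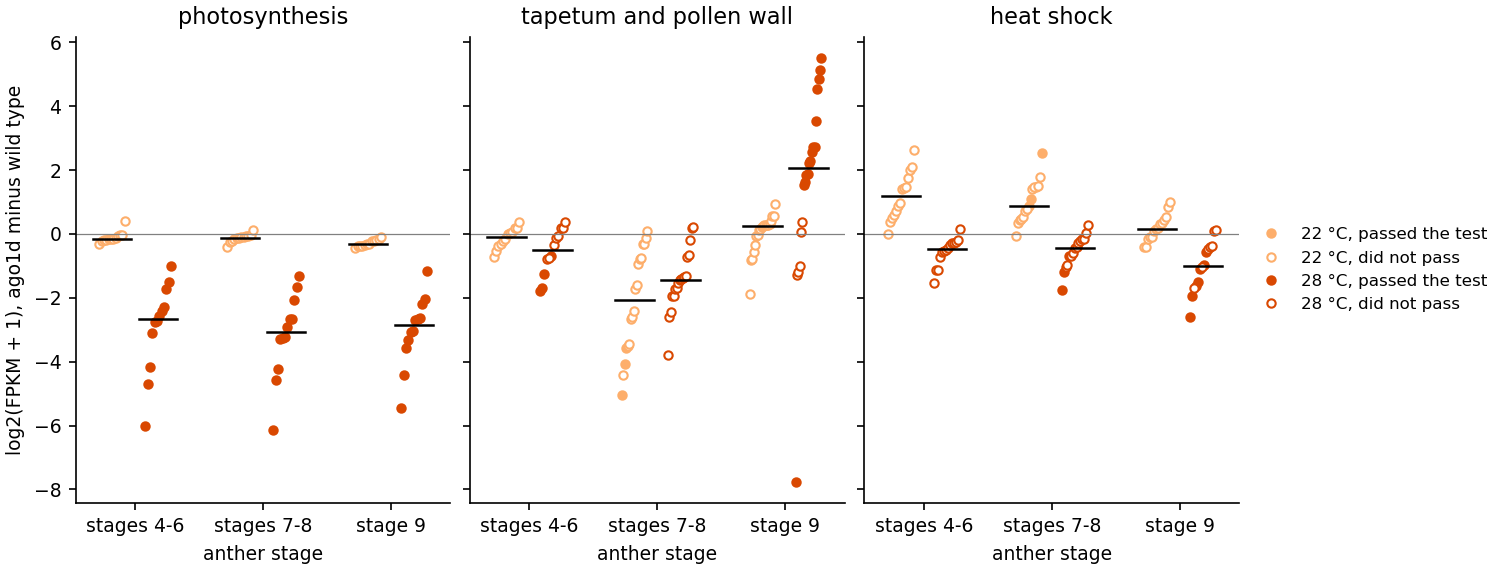
Difference in log2(FPKM + 1) between ago1d and wild type (vertical axis) for each tested member of 3 gene lists by anther stage, at 22 °C (light) and 28 °C (dark). Filled points passed limma's test over all genes, open points did not, and black lines are medians; photosynthesis medians at 28 °C are -2.65, -3.07 and -2.87, and at 22 °C -0.17, -0.12 and -0.31.

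In wild type, some tapetal, meiotic and stress genes differed between 22 °C and 28 °C, though none of their lists was called with an estimated correlation. At stage 9, 12 of 20 tapetum and pollen wall genes were higher at 22 °C and 2 were lower (13 and 2 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). PTC1 was at 32.1 ± 8.05 FPKM at 22 °C and 1.35 ± 0.755 at 28 °C (log2 3.84), and RTS was at 19.1 ± 28.0 against 956.4 ± 280.4 (-6.67). In the same comparison 2 of 8 markers of other floral organs were higher at 22 °C (3 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation), MADS6 by 0.79 and MADS15 by 0.69 on the log2 scale. At stages 7 to 8, 6 of 19 meiosis genes were higher at 22 °C (8 adjusted over the list alone, adjusted p = 0.586 with an estimated correlation), among them DMC1A (3.86 ± 0.709 against 0.734 ± 0.384 FPKM), the synaptonemal complex gene ZEP1 (0.97) and SPO11-1, which makes meiotic breaks (0.70). AGO3 (0.91) and AGO4b (0.39) were higher at stages 7 to 8, within 3 of 25 members of the small RNA machinery (2 adjusted over the list alone), and AGO1b (0.55) and AGO1c (0.62) at stage 9, within 4 higher and 1 lower of 27 (5 and 1 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation).

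The stress and photosynthesis genes of wild type that passed limma's test over all genes were lower at 22 °C, but most members did not pass. Photosynthesis members fell in 3, 4 and 3 of 12 cases at the 3 stage groups (8, 6 and 3 adjusted over the list alone), with adjusted p = 0.369, adjusted p = 0.586 and adjusted p = 0.465 with an estimated correlation. Of heat shock genes, 2 of 15 fell at stages 7 to 8 and 3 of 14 at stage 9 (2 and 3 adjusted over the list alone, adjusted p = 0.586 and adjusted p = 0.465 with an estimated correlation), HSP17.9 at both (-0.88 and -1.26). In the cold and dehydration list 1 of 9, 2 of 11 and 3 of 12 fell (adjusted over the list alone, 1, 2 and 3 fell and 1 rose at stage 9), with adjusted p = 0.574, adjusted p = 0.586 and adjusted p = 0.465 with an estimated correlation. They included the dehydrin LIP9 (-1.25 at stages 7 to 8 and -1.29 at stage 9), the cold-response factor DREB1A (-1.43 at stage 9) and MYBS3 (-0.87, -0.70 and -0.62). Over all genes, limma called 1114 lower and 352 higher at stages 4 to 6, 1584 and 2355 at stages 7 to 8, and 2111 and 2363 at stage 9. Rescaling the libraries to the same median changed the split at stages 4 to 6 to 765 lower and 990 higher. With single libraries left out, the calls ranged from 511 (without 22 °C replicate 2) to 1023 at stages 4 to 6. They ranged from 1220 (without 22 °C replicate 3) to 5448 at stages 7 to 8 and from 1886 (without 22 °C replicate 2) to 3648 at stage 9.

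In ago1d, the comparison of 22 °C with 28 °C ran the other way for photosynthesis genes, and for heat shock genes at stages 7 to 8. At the 3 stage groups 8, 9 and 8 of 12 photosynthesis genes were higher at 22 °C (9, 10 and 9 adjusted over the list alone), with adjusted p = 0.248, adjusted p = 0.0889 and adjusted p = 0.348 with an estimated correlation. CAB1R was at 295.9 ± 144.0 FPKM at 22 °C against 16.3 ± 18.7 at 28 °C at stages 4 to 6 (log2 4.58), and CAB2R at 806.1 ± 115.4 against 62.4 ± 60.9 (4.10). At stages 7 to 8, 10 of 15 heat shock genes were higher at 22 °C (13 adjusted over the list alone, adjusted p = 0.0889 with an estimated correlation), led by HSP24.1 (2.29), HSP17.4 (2.16), the disaggregase HSP101 (2.09) and HSP18.0 (1.66). At stages 4 to 6 and stage 9, 0 of 14 passed limma's test, with 2 and 3 at an unadjusted p under 0.05 (adjusted p = 0.815 and adjusted p = 0.536 with an estimated correlation). Of 18 tapetum and pollen wall genes, 4 were lower at stages 7 to 8 (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.386 with an estimated correlation), AP37 by -3.17. The list's median was lower in replicates 2 and 3 at 22 °C. Replicate 1 (5.91) lay within the 28 °C range of 5.64 to 6.14. Meiosis genes were higher there in 5 of 19 cases (8 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation), with DMC1A at 1.56 and ZEP1 at 0.91.

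Over all genes in ago1d, limma called 358 lower and 196 higher at stages 4 to 6, 847 and 803 at stages 7 to 8, and 339 and 519 at stage 9. With single libraries left out, the calls ranged from 156 (without 22 °C replicate 3) to 587 at stages 4 to 6. They ranged from 385 (without 22 °C replicate 2) to 1365 (without 22 °C replicate 1) at stages 7 to 8, and from 272 (without 22 °C replicate 2) to 1398 (without 22 °C replicate 3) at stage 9.

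Small RNA of 21-PHAS loci was lower in ago1d than in wild type at both temperatures. Summed over the loci and averaged over the stage groups, it stood at a ratio of 0.745 to wild type at 22 °C (log2 -0.42, exact permutation p = 0.0015, 2-sided, 9 libraries against 9) and 0.676 at 28 °C (log2 -0.57, exact permutation p = 0.004). At stages 7 to 8 and 28 °C the sums were 74667 ± 3555 RPM in ago1d and 142527 ± 36218 in wild type (SD, n = 3). This ratio of 0.535 was the lowest of any stage group and temperature. There, and at stages 4 to 6 and 22 °C (ratio 0.724), the groups did not overlap. Elsewhere they overlapped, with ratios of 0.676 and 0.845 at 22 °C (stages 7 to 8 and 9) and 0.753 and 0.766 at 28 °C (stages 4 to 6 and 9). Of the 1842 loci tested, limma called 753, 896 and 765 lower and 66, 52 and 145 higher at the 3 stage groups at 22 °C, and 845, 1143 and 722 lower and 94, 29 and 228 higher at 28 °C. The locus on chromosome 10 from 13965258 to 13965596 fell from 324.7 ± 64.3 RPM to 8.00 ± 1.73 at stages 4 to 6 and 22 °C (log2 -5.18), and from 102.7 ± 10.97 to 1.67 ± 1.15 at stages 7 to 8 and 28 °C (-5.36). The locus on chromosome 11 from 16400510 to 16400868 had log2 changes of -5.28, -5.96 and -5.34 at 28 °C. Loci that rose included chromosome 12 from 21105098 to 21105372, at 97.3 ± 23.3 against 7.67 ± 3.06 RPM at stages 4 to 6 and 22 °C (3.53), and chromosome 6 from 4740187 to 4740628 (1.86). The genome build of these coordinates was not given in the sources used here.

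The files do not state the denominator of the RPM, so a shift shared by the 21-PHAS loci cannot be parted from a shift of scale. After rescaling to the same median, which by construction removes such a shift, the splits were 474 lower and 681 higher, 489 and 718, and 538 and 688 at 22 °C, and 523 and 685, 462 and 690, and 500 and 670 at 28 °C. The medians that rescaling removed were -0.54, -0.77 and -0.48 at 22 °C and -0.69, -1.13 and -0.47 at 28 °C on the log2 scale. One wild-type library of stages 4 to 6 and 22 °C, replicate 1, has labels that disagree on its temperature and was grouped by its title; without it 749 loci were called in place of 819.

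Small RNA of 24-PHAS loci was also lower in ago1d. The summed RPM stood at a ratio of 0.377 to wild type at 22 °C (log2 -1.41, exact permutation p = 0.00025) and 0.450 at 28 °C (-1.15, exact permutation p = 0.00025), which is the smallest p the test allows. The 10 highest loci held 54.4% to 80.8% of the sum, and without them the log2 differences were -0.68 and -0.56 (exact permutation p = 0.00075 and exact permutation p = 0.008). At 22 °C the sums were 2485 ± 777, 3363 ± 479 and 4253 ± 388 RPM in ago1d and 4580 ± 498, 9668 ± 765 and 14503 ± 1743 in wild type (SD, n = 3). Of 50 loci, limma called 20, 32 and 30 lower and 4 higher at each stage group at 22 °C, and 29, 34 and 17 lower and 4, 3 and 8 higher at 28 °C. The locus on chromosome 5 from 1028152 to 1028488 was at 4.00 ± 1.73 RPM in ago1d and 759.7 ± 52.0 in wild type at stages 7 to 8 and 22 °C (log2 -7.32), and the locus on chromosome 12 from 22749563 to 22749827 at 9.00 ± 4.36 against 439.3 ± 43.6 (-5.54). The locus on chromosome 7 from 7563279 to 7563567 was higher, at 212.3 ± 40.8 against 21.7 ± 2.52 RPM (3.22). Rescaling changed the splits to 15 lower and 13 higher, 14 and 16, and 15 and 24 at 22 °C, and to 12 and 28, 11 and 25, and 12 and 27 at 28 °C, with the same construction. The small RNA library of wild type at stages 4 to 6 with the label conflict enters these 22 °C values.

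**Figure D3:**
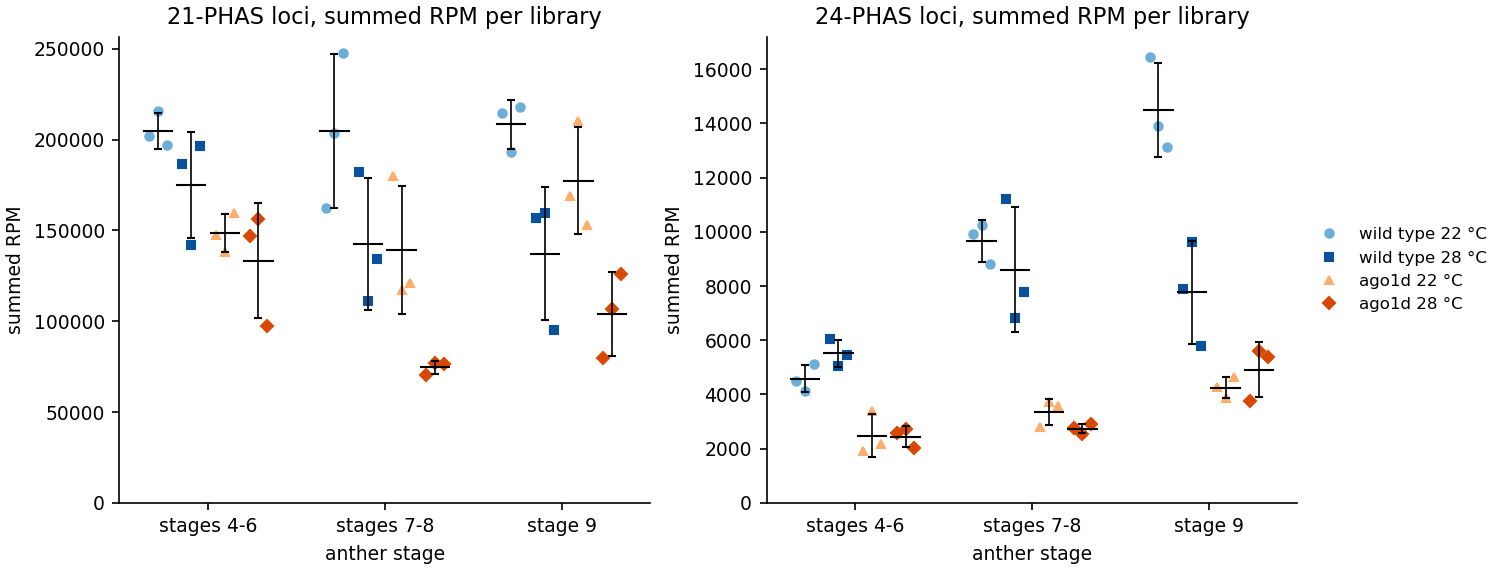
Summed RPM of 21-PHAS loci (left) and 24-PHAS loci (right) in each of the 36 small RNA libraries by anther stage; points are libraries, horizontal lines group means and bars 1 SD (n = 3). For 24-PHAS loci at 22 °C and stage 9, ago1d lies at 4253 ± 388 RPM and wild type at 14503 ± 1743.

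The loci that fell at 22 °C and at 28 °C were largely shared. Of the 21-PHAS loci called lower, 693, 862 and 625 were lower at both temperatures, against 345.4, 556 and 299.9 for independent lists. The comparisons share no libraries, but both take the spread of each locus from the same fit. Loci of low spread are thus more readily called in both, so independent lists are not an exact baseline. Across loci, which are not independent replicates, the log2 changes at the 2 temperatures had Spearman correlations of 0.921, 0.901 and 0.870 for 21-PHAS and 0.955, 0.950 and 0.922 for 24-PHAS. Across genes the corresponding values were 0.144, 0.293 and 0.330.

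The RPM of 21-PHAS loci also differed between temperatures, and here too a shift shared by the loci cannot be parted from a shift of scale. In wild type the summed 21-PHAS RPM at 22 °C was 1.39 times that at 28 °C (log2 0.47, exact permutation p = 0.002), and in ago1d 1.53 times (0.61, exact permutation p = 0.0015). In wild type limma called 2, 36 and 746 21-PHAS loci higher at 22 °C and 0, 0 and 3 lower, with 189, 377 and 893 loci at an unadjusted p under 0.05. The locus on chromosome 12 from 21014659 to 21014933 was at 543.3 ± 83.3 RPM at 22 °C and 54.3 ± 26.1 at 28 °C at stage 9 (log2 3.39), and the locus on chromosome 7 from 8720573 to 8720951 at 403.0 ± 28.8 against 54.0 ± 29.8 (3.06). In ago1d, 17, 715 and 640 loci were higher and 0, 2 and 0 lower, with 212, 950 and 961 at an unadjusted p under 0.05. Rescaling changed these to 36 lower and 31 higher, 16 and 18, and 205 and 231 in wild type, and to 25 and 51, 16 and 51, and 7 and 2 in ago1d. Single libraries moved them widely: the 749 calls at stage 9 in wild type became 385 without 28 °C replicate 3, and the 640 in ago1d became 15 without 28 °C replicate 1. In ago1d the 717 calls at stages 7 to 8 became 242 without 22 °C replicate 1. In wild type the 36 became 225 without 28 °C replicate 1 and 0 without 22 °C replicate 3, and the 2 at stages 4 to 6 became 0 without 22 °C replicate 1, the library whose labels disagree.

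For 24-PHAS loci in wild type, the calls between temperatures were mostly lower at 22 °C at stages 4 to 6 and all higher at stage 9. No test compared the stage groups. At stages 4 to 6, 14 loci were lower and 1 higher at 22 °C, at stages 7 to 8, 2 and 2, and at stage 9, 0 and 28, with 19, 9 and 28 at an unadjusted p under 0.05 (limma). The chromosome 5 locus from 1028152 to 1028488 was higher at 22 °C at each stage group (log2 0.90, 1.60 and 2.16), and at stage 9 stood at 726.0 ± 96.0 RPM against 163.7 ± 39.7. In ago1d, 2 loci were lower and 5 higher, 3 and 13, and 0 and 3, with 13, 21 and 7 at an unadjusted p under 0.05. Averaged over the stage groups, the summed 24-PHAS RPM gave a log2 difference of 0.29 in wild type (exact permutation p = 0.112, and 0.0437 without 28 °C replicate 1 of stages 7 to 8) and 0.03 in ago1d (exact permutation p = 0.802). By stage group the wild-type values were -0.27 and 0.20, with overlapping groups, and 0.93 at stage 9. The stage 9 sums were 14503 ± 1743 RPM at 22 °C and 7763 ± 1916 at 28 °C and did not overlap. The median over loci gave -0.05 in wild type (exact permutation p = 0.821) and 0.44 in ago1d (exact permutation p = 0.00675). Rescaling changed the splits to 1 lower and 10 higher, 3 and 7, and 5 and 8 in wild type, the same direction at each stage group. In ago1d it changed them to 17 and 3, 18 and 2, and 0 and 2. Single libraries moved the 15 calls at stages 4 to 6 in wild type to 1 (without 22 °C replicate 2 or 28 °C replicate 1), 2 (without 28 °C replicate 3) and 6 (without 22 °C replicate 1, whose labels disagree). They moved the 28 at stage 9 to 16 (without 28 °C replicate 3).

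Whether the effect of ago1d on PHAS loci depended on temperature was tested as an interaction. For 21-PHAS loci limma called 0, 0 and 3 of 1842, with 65, 160 and 194 at an unadjusted p under 0.05. For 24-PHAS loci it called 1, 1 and 16 of 50, and the 16 at stage 9 were all negative, the difference from wild type being more negative at 22 °C. After rescaling the 21-PHAS totals were 4, 1 and 121, the last with 85 negative and 36 positive, and the 24-PHAS totals 15, 9 and 2. Without wild type 28 °C replicate 3, 2 of the 16 calls at stage 9 were made.

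In the RIP, 21-nt phasiRNAs bound to AGO1d-FLAG were mostly those beginning with U. U made up 58.9% ± 4.55 of the summed 21-nt RPM in RIP and 33.2% ± 5.82 in input (SD, n = 9 pairs), higher in 9 of 9 pairs (exact sign-flip adjusted p = 0.00521). Its means in RIP and input were 64.72% and 28.38% at stages 4 to 6, 55.67% and 30.43% at stages 7 to 8, and 56.29% and 40.83% at stage 9. No test compared the stage groups. C was lower, at 30.0% ± 3.99 against 39.0% ± 2.38, and G at 0.43% ± 0.07 against 9.97% ± 2.56, each in 9 of 9 pairs (exact sign-flip adjusted p = 0.00521). A was lower by 7.07 percentage points in 8 of 9 pairs, at 10.7% ± 3.24 against 17.8% ± 2.81 (exact sign-flip adjusted p = 0.0156). Its means in RIP and input were 8.15% and 21.16% at stages 4 to 6 and 9.35% and 17.23% at stages 7 to 8. At stage 9 they were close, at 14.62% and 14.95%. Counting sequences in place of RPM, the difference of A was -2.99 points and did not pass (exact sign-flip adjusted p = 0.0625). Nor did the RPM difference pass with stages 4 to 6 left out (-4.10 points) or stages 7 to 8 left out (-6.66), each at exact sign-flip adjusted p = 0.125 over 6 pairs.

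Single 21-nt phasiRNAs were enriched or depleted strongly and repeatedly. TTGTATAGTTGTAAGGTGTGC was at 101.0 ± 43.4 RPM in RIP and 1.67 ± 0.577 in input at stages 4 to 6 (log2 5.20, n = 3), and its changes at the other stage groups were 5.15 and 4.20. GAAAGCGATCTACGGAATGAT was at 2.67 ± 1.15 RPM in RIP and 506.0 ± 279.1 in input (log2 -6.94), with changes of -5.74 and -4.99 later. Of 15575, 12657 and 8313 phasiRNAs tested, limma called 1979, 2741 and 1333 enriched and 5937, 1779 and 1876 depleted. Rescaling changed the split at stages 4 to 6 to 3287 enriched and 4610 depleted. Summed over all 21-nt phasiRNAs, RIP was lower than input in 6 of 9 pairs and did not pass (log2 -0.06 ± 0.44, exact sign-flip p = 0.695). The direction differed by stage group. Mean sums in RIP and input were 76503 and 106200 RPM at stages 4 to 6 and 36106 and 39545 at stage 9. At stages 7 to 8 RIP was higher, at 89562 against 67252 RPM. With stages 7 to 8 left out the log2 ratio was -0.30 ± 0.27, lower in 6 of 6 pairs (exact sign-flip p = 0.0312). With stages 4 to 6 left out it was 0.15 ± 0.34. No test compared the stage groups.

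PhasiRNAs of 24 nt were depleted in the RIP. Their summed RPM was at a ratio of 0.147 to input, lower in 9 of 9 pairs (log2 -2.77 ± 0.70, SD, n = 9; exact sign-flip p = 0.00391), a sum chosen after the data had been seen. Of 697, 894 and 722 tested, limma called 574, 557 and 480 depleted and 2, 6 and 13 enriched. CAGAGATTTAGTTAAGACAGAACT was at 3.00 ± 2.00 RPM in RIP and 829.7 ± 192.5 in input at stages 7 to 8 (log2 -7.81). TTATTAAGTTGGATTGGTAGCCAT, which begins with U in the RNA, was enriched, at 112.3 ± 6.51 against 41.0 ± 14.4 RPM at stages 7 to 8 (1.49) and 94.3 ± 11.2 against 24.7 ± 5.13 at stage 9 (1.91). Rescaled to the same median, the splits were 116 depleted and 120 enriched, 106 and 301, and 121 and 297. This rescaling removes a depletion of the whole class by construction. Within the 24-nt class, U rose from 19.0% ± 4.82 of the summed RPM in input to 39.8% ± 7.12 in RIP, in 9 of 9 pairs (exact sign-flip adjusted p = 0.00521). C and G fell by 7.60 and 3.62 percentage points in 9 of 9 pairs each (exact sign-flip adjusted p = 0.00521). A fell by 9.56 points in 8 of 9 pairs (exact sign-flip adjusted p = 0.0195), but rose by 4.44 points when sequences were counted in place of RPM (exact sign-flip adjusted p = 0.0156). This fall did not pass with stages 7 to 8 left out (-7.01 points) or stage 9 left out (-8.44), each at exact sign-flip adjusted p = 0.125 over 6 pairs.

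**Figure D4:**
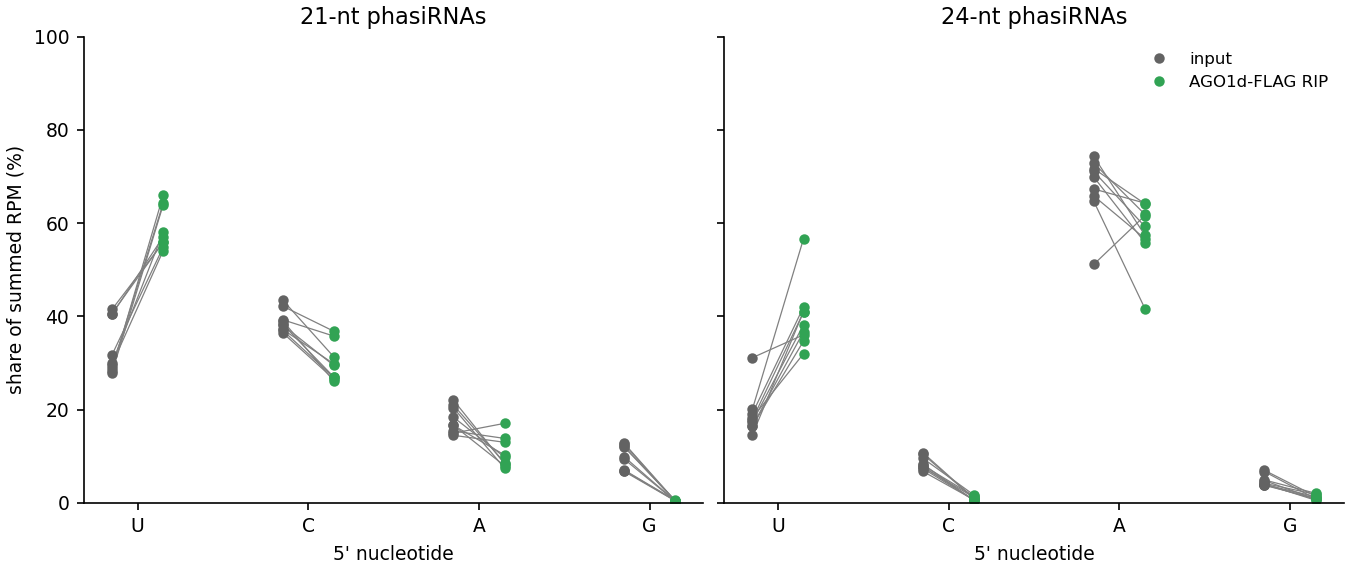
Share of summed RPM by 5′ nucleotide (vertical axis, percent) for 21-nt (left) and 24-nt (right) phasiRNAs in input (grey) and AGO1d-FLAG RIP (green); points are libraries and lines join the RIP and input of 1 lysate. The share of U is higher in RIP in 9 of 9 pairs for both lengths, with means of 58.9% against 33.2% at 21 nt and 39.8% against 19.0% at 24 nt.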

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

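Chosen after the results were seen were the test of carried-over floral tissue, the test of loci with a mean of at least 20 RPM, all counts of sample splits, and the 24-PHAS interactions.

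Photosynthesis genes passed the test between ago1d and wild type at 28 °C and not at 22 °C, and the difference itself passed the interaction test for 9, 11 and 6 of 12 members at stages 4 to 6, 7 to 8 and 9. Less carried-over lemma, palea or other floral tissue in the ago1d libraries would lower the markers of those organs as well. The lowest of their 3 median log2 changes was 0.076 and no marker fell below -0.501, against photosynthesis medians of -2.65 and lower. This argues against a loss of tissue in which these markers are expressed. The markers are organ and meristem identity genes, and the test was set when their medians were known. Less green tissue that expresses them little stays open. A single library does not set the fall of photosynthesis genes: with any of the 6 libraries left out at least 11 of 12 members were called. An undocumented difference in background or light between the plants was not tested and stays open.

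Genes changed between ago1d and wild type at stage 9 and 28 °C in larger numbers than elsewhere, and the tapetum list had an interaction there for 4 members. A difference in developmental timing is a candidate explanation: across genes the change had a Spearman rho of 0.292 with the change from stage 9 back to stages 7 to 8 in wild type at 22 °C, which uses other libraries, and 2566 of 4074 called genes had the same sign. Over the called genes alone rho was 0.151, and the correlation was not particular to this comparison: 22 °C against 28 °C in ago1d gave 0.336 (0.535 over its called genes). The tapetum list moved against the axis, with a median of -1.94 along it and 2.06 in ago1d. That does not limit timing, since the axis ends at stage 9 and an older wild type at 28 °C stays open: PTC1 was at 31.6 FPKM in ago1d at 28 °C, 32.1 in wild type at 22 °C and 1.35 in wild type at 28 °C. With 1 library left out, at least 2090 of the 4074 calls were made again, which only just met the bound set beforehand. The calls thus do not all come from 1 library, but their number depended strongly on single libraries. Timing set by ago1d and timing set by sampling cannot be separated here.

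More 21-PHAS loci were lower than higher in ago1d at both temperatures. One scaling factor per library does not account for the changes as such, because at least 62.5% of loci were still called after rescaling, and the 10 highest loci do not carry them, because the log2 difference of the summed RPM without them was still -0.478 or lower. The balance between lower and higher loci is fixed by the rescaling itself, so whether the RPM denominator sets the excess of lower loci stays open. Rounding near the floor does not account for the 1077 loci with a mean of at least 20 RPM, of which at least 35.1% were called lower in each of the 6 comparisons. It stays open for the other 765, where the share called lower was higher, at a lowest ratio of 0.694 between the 2 sets.

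The genotype difference depended on temperature for 133, 302 and 582 genes at the 3 stage groups, by limma's interaction test. Swapping labels at 1 temperature turns the genotype effect itself into an interaction, so the splits were made after the genotype difference shared by both temperatures had been removed. Of 100 drawn splits of the samples only the real one, 1 of 100, gave as many at each stage group. The highest others were 2, 12 and 6, so a chance division of the libraries rarely gave such counts. The splits keep the real interaction in the values, where it adds spread and can lower the other counts. They also cannot tell a genotype effect that depends on temperature from another reason for a group to stand apart. Without removal of the shared genotype difference, as first run, 5, 4 and 7 of 100 gave as many (highest others 601, 1507 and 3905), which carries the genotype effect and does not decide. The stage 9 count was 192 without ago1d 28 °C replicate 2 and 1958 without ago1d 22 °C replicate 3.

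Of 21-PHAS loci, 3 were called for such an interaction at stage 9, and of 24-PHAS loci 1, 1 and 16 at the 3 stage groups. As many came from 5 of 100 drawn splits for the 21-PHAS loci and from 6, 2 and 2 for the 24-PHAS loci. Another split reached each of these counts, so none is read as more than chance. Without wild type 28 °C replicate 3, the 16 at stage 9 were 2. Heat shock genes had an interaction in 6 cases at stages 7 to 8 and 1 at stage 9, the small RNA machinery in 1 at stages 7 to 8 (AGO2), and anther transcription factors in 3 at stage 9.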

How the results depend on the processing

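Chosen after the data were seen were the runs over all RIP lengths, stage groups left out of the RIP sums, placed list members alone, the block for lists and all 24-PHAS values for ago1d 22 °C against 28 °C and the interaction. Stage groups are written s6 (stages 4 to 6), s8 (7 to 8) and s9 (9). The total calls of ago1d against wild type for genes and PHAS loci stayed within 1.5 times under the pseudocount, filter, block and rescaling, except 24-PHAS loci at 28 °C in s9 (39 rescaled, main 25). Their direction did not stay under rescaling, which by construction removes a shared shift. For 21-PHAS loci in each comparison, and 24-PHAS loci at 28 °C, calls went from mostly lower to mostly higher. Calls of 24-PHAS loci at 22 °C became slightly more often higher than lower in s8 and clearly so in s9. In s6 slightly more stayed lower than higher. For 21-PHAS loci at 22 °C in s6, 753 lower and 66 higher became 474 and 681. Except where a construction is named, the cause was not tested. Unknown depth leaves open how much of the spread at low RPM is counting error.

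Rescaled to the same median, 21-PHAS calls were 67 (s6) and 436 (s9) for temperature in wild type, 76, 67 and 9 in ago1d and 4, 1 and 121 for the interaction. The 24-PHAS calls were 10 (s8) and 13 (s9) for temperature in wild type, 20 (s6) in ago1d and 15, 9 and 2 for the interaction, and 24-nt RIP calls in s6 were 236. With a pseudocount of 0.1, 21-PHAS calls were 21 (wild type s8), 30 (ago1d s6) and 4 (interaction s8), and 24-PHAS calls 9 and 1 (wild type s6, s8), 1 (ago1d s9), 0 and 9 (interaction s8, s9). With no filter, gene interactions were 80 (s6) and 351 (s9), where more genes were tested. With the 12 libraries of a stage group alone, 21-PHAS calls were 34 (wild type s6), 91 and 131 (ago1d s6, s9), 8 and 0 (interaction s6, s9), and 24-PHAS calls 7 (wild type s6), 2 and 0 (interaction s6, s8).

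Replicate numbers of the RNA-seq and small RNA libraries were not treated as pairs, because not every same-number correlation was over 0.1. They ran from -0.117 to 0.470 for genes (10, 8 and 9 of 18 pairs over 0.1), with medians of 0.105, 0.094 and 0.105 against -0.046, -0.044 and -0.038 for different numbers, a hint of a partly shared structure. They ran from -0.144 to 0.140 for 21-PHAS and from -0.375 to 0.206 for 24-PHAS loci. Of the libraries, 7, 9 and 5 of 12 in RNA-seq, 10 of 36 for 21-PHAS and 3 of 36 for 24-PHAS correlated best with their own number. With the replicate block, temperature calls in wild type were 1 and 23 (21-PHAS s6, s8) and 6 and 2 (24-PHAS s6, s8), the 24-PHAS interaction in s8 was 0, and list calls were 64. No other count moved by over 1.5 times under the block, RIP included.

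Over all lengths, RIP calls were 12235, 6958 and 5452 (21-nt tables) and 986, 1005 and 935 (24-nt tables), where more sequences were tested. List calls fell from 59 to 5 with an estimated correlation and were 45 with placed members alone, or 3 with both. With both, photosynthesis (2 members) lost the call in ago1d against wild type at 28 °C (s6, s8) and in the interaction (s6), and heat shock gained it in ago1d against wild type at 22 °C (s8). By the median over loci, the 24-PHAS temperature difference was -0.048 in wild type and 0.441 in ago1d. Counting sequences, the 5′ A difference was -2.99 at 21 nt and 4.44 at 24 nt. By RPM, the difference lost its call at 21 nt without s6 (-4.10) or s8 (-6.66) and at 24 nt without s8 (-7.01) or s9 (-8.44), each at adjusted p = 0.125. The summed 21-nt RIP log2 ratio was 0.148 without s6 and -0.302 without s8.

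With each library left out in turn, genes called were 131 to 237 in s8 and 155 to 1218 in s9 for ago1d against wild type at 22 °C. They were 495 to 869 in s6, 1030 to 2359 in s8 and 2108 to 5016 in s9 for ago1d against wild type at 28 °C. They were 511 to 1023 in s6, 1220 to 5448 in s8 and 1886 to 3648 in s9 for temperature in wild type. They were 156 to 587 in s6, 385 to 1365 in s8 and 272 to 1398 in s9 for temperature in ago1d. They were 71 to 227 in s6, 185 to 370 in s8 and 192 to 1958 in s9 for the interaction. With each library left out in turn, 21-PHAS loci called were 0 to 3 in s6, 0 to 225 in s8 and 385 to 779 in s9 for temperature in wild type. They were 0 to 15 in s6, 242 to 704 in s8 and 15 to 855 in s9 for temperature in ago1d. They were 0 to 1 in s6, 0 to 2 in s8 and 0 to 39 in s9 for the interaction. With each library left out in turn, 24-PHAS loci called were 1 to 15 in s6, 2 to 4 in s8 and 16 to 28 in s9 for temperature in wild type. They were 2 to 10 in s6, 10 to 14 in s8 and 0 to 4 in s9 for temperature in ago1d. They were 0 to 3 in s6, 0 to 1 in s8 and 2 to 19 in s9 for the interaction.
The summed 24-PHAS temperature difference ran from 0.219 to 0.354 in wild type, where it passed without s8 28 °C replicate 1 (exact permutation p = 0.0437, 0.112 with all libraries), and from -0.049 to 0.085 in ago1d, where it was -0.049 without s6 22 °C replicate 2, -0.013 without s6 28 °C replicate 3 and -0.030 without s9 28 °C replicate 1. Libraries behind most of the extremes of the gene and 21-PHAS counts are named beside those counts in the report. The other values of left-out libraries were 369 in all, against 131 counts of calls that moved by over 1.5 times. Among the 369, counts of calls stayed within 1.5 times. Summed PHAS differences kept their sign and their side of the threshold of 0.05. Of 3272 values for the named genes, loci and phasiRNAs over all settings, 2890 kept their call and direction, 378 kept the direction and lost the call, 4 gained the call and 0 changed direction. Most of these items were picked for large changes past the threshold in the same data, which makes a change of direction unlikely from the start.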

Other observations

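All counts of sample splits, and the reading of the lists below, were chosen after the results were seen.

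Stamen identity genes, the MADS-box factors that specify the stamen, tended to be lower in ago1d at 22 °C and stage 9. None of the 5 passed limma's test over all genes, 4 had an unadjusted p under 0.05 and 4 were lower when adjusted over the list alone, and the median log2 change was -0.36 (adjusted p = 0.433 with an estimated correlation). Cold and dehydration genes in ago1d against wild type at 28 °C and stage 9 had 1 of 12 members lower (1 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation), MYBS3 (-0.59).

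Wild-type anthers at 28 °C stood apart from the other 3 groups on the first principal component of RNA-seq, at 37.8 to 44.9 at stages 4 to 6 and 73.4 to 78.4 at stage 9. Those of stages 7 to 8 were at 79.7, 50.4 and 17.2, and replicate 2 (17.2) lay close to an ago1d library of 28 °C at 10.6, so the groups were less apart there. One ago1d library of stages 4 to 6 and 28 °C, replicate 1, stood at 70.5 on the second component, where no other library of that stage group exceeded 8.51.

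With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The values below give the real number of calls at the 3 stage groups and, against it, the highest of the other splits. Genes gave 121, 249 and 348 against 1, 3 and 2 for ago1d against wild type at 22 °C, and 835, 1485 and 4074 against 1, 68 and 1 for ago1d against wild type at 28 °C. They gave 1466, 3939 and 4474 against 0, 11 and 0 for 22 °C against 28 °C in wild type, and 554, 1650 and 858 against 1, 1 and 2 for 22 °C against 28 °C in ago1d. The 21-PHAS loci gave 819, 948 and 910 against 0, 0 and 0 for ago1d against wild type at 22 °C, and 939, 1172 and 950 against 0, 1 and 124 for ago1d against wild type at 28 °C. They gave 2, 36 and 749 against 0, 263 and 0 for 22 °C against 28 °C in wild type, and 17, 717 and 640 against 0, 7 and 2 for 22 °C against 28 °C in ago1d. The 24-PHAS loci gave 24, 36 and 34 against 1, 0 and 1 for ago1d against wild type at 22 °C, and 33, 37 and 25 against 0, 0 and 1 for ago1d against wild type at 28 °C. They gave 15, 4 and 28 against 0, 0 and 1 for 22 °C against 28 °C in wild type, and 7, 16 and 3 against 1, 1 and 0 for 22 °C against 28 °C in ago1d. The 21-nt phasiRNAs in RIP gave 7916, 4520 and 3209 against 0, 0 and 0. The 24-nt phasiRNAs in RIP gave 576, 563 and 493 against 0, 0 and 10. The real split was the highest, 1 of 10, in each case but 21-PHAS loci of wild type at stages 7 to 8, where 2 of 10 splits gave as many.

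For the interactions of PHAS loci 100 splits were drawn, with the shared genotype difference removed as for genes. For 21-PHAS loci the real counts at the first 2 stage groups were 0, which all 100 splits match by construction, so nothing can be said about chance there (highest others 0 and 1). The real 3 at stage 9 came from 5 of 100 splits (highest other 295), so chance cannot be excluded. What produced the split with 295 calls was not tested. For 24-PHAS loci, as many as the real 1, 1 and 16 came from 6, 2 and 2 of 100 (highest others 9, 1 and 19), so chance cannot be excluded at stages 4 to 6. The later 2 counts are not read as more than chance either, because another split reached each of them. Without that removal, as first run, 100, 100 and 18 of 100 splits gave as many for 21-PHAS loci and 14, 12 and 13 for 24-PHAS loci. The single locus at stages 7 to 8 was not called with the replicate block or with a pseudocount of 0.1, and the 16 at stage 9 were 2 without wild type 28 °C replicate 3 and 2 after rescaling.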
